A study of Danio rerio with 3 samples.

How the data were processed

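Cells positive for a dsRed reporter under fli1a regulatory sequence were sorted from digested anal fins of immature zebrafish into plates of 384 wells, and 3 plates of single-cell RNA libraries were made by MARS-seq, per the labels' protocols. MARS-seq is a plate-based method in which a well barcode and a unique molecular identifier (UMI) tag the 3' end of each captured poly(A) transcript before pooling. The labels name 80 dissected fins for each plate and do not say whether the plates came from separate fish. The p-values of the contrasts therefore refer to 3 plates, whose spread may be technical. The edgeR test used for them moderates the spread of each gene towards that of other genes. A small p of a single gene thus also reflects its UMI counts and does not measure that gene's own spread over plates. The deposited plate tables give all plates the same sequencing batch.

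The authors deposited, for each plate, a table of UMI counts per gene and well with no normalization. Bowtie2 and the zebrafish build GRCz10 are named in the submitters' processing notes, without a version for Bowtie2. The gene annotation, the UMI collapsing rule and the read filters are not given in the sources used here. Accompanying tables pair each column with a well coordinate and cell barcode, and list the wells that the authors analysed. That list held 384, 384 and 268 wells of plates 1, 2 and 3, and these 1036 of 1152 wells entered the clustering and the contrasts between classes unless another set is named, while the comparison of matching coordinates also drew on wells off the list. The tables hold 25839 rows, of which 16029 had a UMI in some well. All 92 rows for spike-in RNA were at 0. The tables mark no wells as empty, so the planned background from wells without a cell could not be measured. A group of 19 rows with clone names, among the most abundant in the tables, was treated as mitochondrial ribosomal RNA on the strength of that abundance. No coordinates are printed, because the reference table used for gene synonyms follows another assembly than the deposited counts. Where a planned symbol had no row, its synonym in that table was used. In this way plvapb was read from the row vsg1, plvapa from si:dkey-208k22.3 and cavin2b from sdprb. The symbol fabp4a shared the row fabp11a.

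Each UMI of each well was assigned at random, with probability 0.5 (seed 1), to a set that made the clusters or to a held-out set that was tested. Clusters came from the first set alone in scanpy 1.11.5 on Python 3.11.15. Counts were scaled to the median well and log-transformed, and 1500 variable genes were kept without spike-in, mitochondrial and ribosomal protein genes. Then followed 20 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (leidenalg 0.10.2). The split makes tested UMIs independent of the clustering if UMIs follow Poisson sampling, and overdispersed counts would leave some dependence. In a simulation without classes, edgeR tests on the held-out set called 0 of 215 genes (12 at an unadjusted p under 0.05). Clusters and tests on the same UMIs called 8 of 1078 (41 at an unadjusted p under 0.05). These simulated tests differ in depth and in the number of genes, so 0 against 8 calls does not show that the split removed dependence.

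The lists of cell type markers, the gene lists, the test, its block and the rule for named genes were fixed before the data were examined. The rule that turned marker levels into cluster names was not. It was written after marker levels by cluster had been viewed at several settings, the held-out set included, and was revised after a cluster with a few neutrophil-rich wells had taken a neutrophil name. A cluster was called LEC-like or BEC-like by its mean log2 marker level relative to the wells outside it. The level of lymphatic markers had to exceed that of blood markers, or the reverse, by more than 0.5. At least 3 markers of that kind had to be raised 1.25-fold. The top 10 genes also had to hold no fewer markers of that kind than of the opposite kind or any other cell type. Another cell type needed 3 markers among the top 10 genes and a UMI of that type in at least 50% of wells. With 3 such markers but fewer such wells, a cluster stayed unnamed. Clusters 5 and 6 met the LEC-like marker levels and stayed unnamed through these conditions. Cluster 5 had 5 neutrophil markers among its top 10 genes, and cluster 6 had 1 keratinocyte marker, krt4. Clusters of low depth without a marker of the type among their top 10 genes stayed unnamed. The naming markers are left out of the counts of genes called between the classes and, by a choice made after the first counts had been seen, against unnamed clusters. The counts between clusters of the same class include them.

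Held-out UMIs were summed per plate and class and tested in edgeR 4.0.16 (R 4.3.3) with TMM scaling, the default expression filter and the quasi-likelihood F-test, with plate as a block, since both classes of a plate share its sort and library. A class entered with at least 10 wells in each plate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. After removal of class means, the sums of the 2 endothelial classes correlated across genes at 0.127, 0.0467 and 0.0748 within plates 1, 2 and 3. For each contrast the text names up to 12 genes per direction with the largest fold among those called, moving the same way in all 3 plates and reaching 20 CPM. Up to 3 called members of each tested list were added, as were the naming markers and, whatever their p, sox17, sox7, sox18, prox1a, nr2f2, mki67 and pcna. Clone-named, ribosomal protein, mitochondrial and spike-in rows were left out of the fold ranking. Levels (CPM) are UMIs of a gene per 1000000 UMIs of the held-out sum, as mean ± SD of 3 plates.

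Gene lists were tested in limma 3.58.1 with camera at a preset inter-gene correlation of 0.01, with the correlation estimated as a check, and with fry, for lists of at least 5 measured members after removal of naming markers. Of the lists planned, those for Notch, SoxF and ETS factors, basement membrane, scavenging and endocytosis, junctions, transport and barrier, glycolysis, oxidative phosphorylation, dissociation stress and actin reached that size between the endothelial classes. Camera sets a list against other genes. The directional p of fry asks whether the genes of a list move, on balance, one way.

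The edgeR step was tested on simulated counts drawn from the means, the depths and edgeR's own estimates of dispersion in each contrast. In each, 200 genes were shifted 2-fold or 4-fold at random, of which those passing the filter were scored. Because the simulated spread was edgeR's own estimate, recovery and false calls cannot show whether that estimate understates the spread between plates. Between the endothelial classes it recovered 74.4% of 2-fold and 100% of 4-fold changes among 1023 genes, with 4 false calls. Recovery of 2-fold changes was 58.9%, 56.8% and 60.0% against unnamed clusters 3, 5 and 6 (370, 364 and 363 genes). Between the subclusters it was 56.8% for LEC-like wells (721 genes) and 88.9% for BEC-like wells (219 genes).

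Shares of wells carry exact Clopper-Pearson 95% intervals, which cover counting error only. For co-detection of lymphatic and blood markers each well was thinned to 500 UMIs in 20 draws, and shallower wells were left out. No doublet caller was run, and doublets were weighed by depth instead. The alternatives were DESeq2 1.42.0, its size factors in edgeR, no expression filter, no plate block, each plate left out, other random splits (seeds 2 and 3), no split, all wells with at least 500 UMIs in place of the authors' list, resolutions 0.5 and 2.0, and classes by marker sums. Chosen after seeing the data were the comparison of the BEC-like subclusters, the contrast within only the malat1-rich or malat1-poor clusters, leaving out 3 wells rich in globin mRNA, and co-detection without plvapb or within each class. Planned comparisons of arterial-like with other BEC-like wells and of neutrophil-like with endothelial wells were not run. At the reported settings no BEC-like cluster had an arterial marker among its top 10 genes, and no cluster met the neutrophil rule. With seed 3 and at resolution 2.0, a BEC-like cluster had 2 and 1 arterial markers there. Figures were drawn with matplotlib 3.10.9.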

Results

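Endothelial cells of the growing zebrafish anal fin were profiled well by well on 3 plates, in a series whose title concerns specialised blood vessels that arise from lymphatic vessels. Reporter-positive cells were sorted on fli1a, an ETS transcription factor gene active in endothelium. The plates are repeats of 1 group, so every comparison below is between classes of wells within the plates. The 3 plates held 559559, 481392 and 221176 UMIs. Median depth of the wells analysed was 1064.5, 914.5 and 382 UMIs per well, and plate 3 was the shallowest. Across 4328 genes, log2 levels of plates 1 and 2 correlated at Pearson's r = 0.952, and those of plate 3 with plates 1 and 2 at 0.887 and 0.879, over genes that are not independent replicates. A chi-square statistic per degree of freedom of 1.93 to 4.14 put all pairs of plates beyond sampling noise. Wells at the same coordinate of different plates, which carry the same barcode, had a mean profile correlation of 0.0453 over 1454 genes, against 0.00045 for shuffled wells. Thinned to 300 UMIs, the correlation was 0.0159 against -2.9e-05.

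Clustering gave 4 endothelial clusters in 2 classes. In the LEC-like class, lymphatic markers had a higher mean log2 level than blood markers, each relative to the wells outside the cluster. This class held 497 wells, or 47.0% ± 8.03 of the wells of a plate (SD, n = 3). The BEC-like class, in which blood markers had the higher level by that measure, held 289 wells, or 27.1% ± 6.51. Unnamed clusters held 17.2%, 18.5% and 42.2% of plates 1, 2 and 3, with exact 95% intervals of 13.5 to 21.3, 14.7 to 22.7 and 36.2 to 48.3. The naming markers lyve1a, mrc1a, stab1 and nrp2a, endocytic and guidance receptors of lymphatic endothelium, were higher in LEC-like sums, at 1277 ± 423 against 395 ± 114 CPM (UMIs per 1000000 held-out UMIs) for lyve1a. The naming markers aqp8a.1 and aqp1a.1, water channel genes, and plvapa, esm1, kdrl and plvapb were higher in BEC-like sums, at 16055 ± 1092 against 1384 ± 155 for aqp8a.1. Each name rests on that relative level and not on the sum of marker UMIs, since in LEC-like sums blood markers still totalled more than lymphatic markers, at 5510 ± 598 against 3910 ± 435 CPM. Counted by UMIs of single wells, blood markers led in 333 LEC-like wells and lymphatic markers in 88. Of all wells, 255 with a marker UMI lay within 1 UMI of a tie, and a further 199 had no UMI of either kind.

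**Figure D1:**
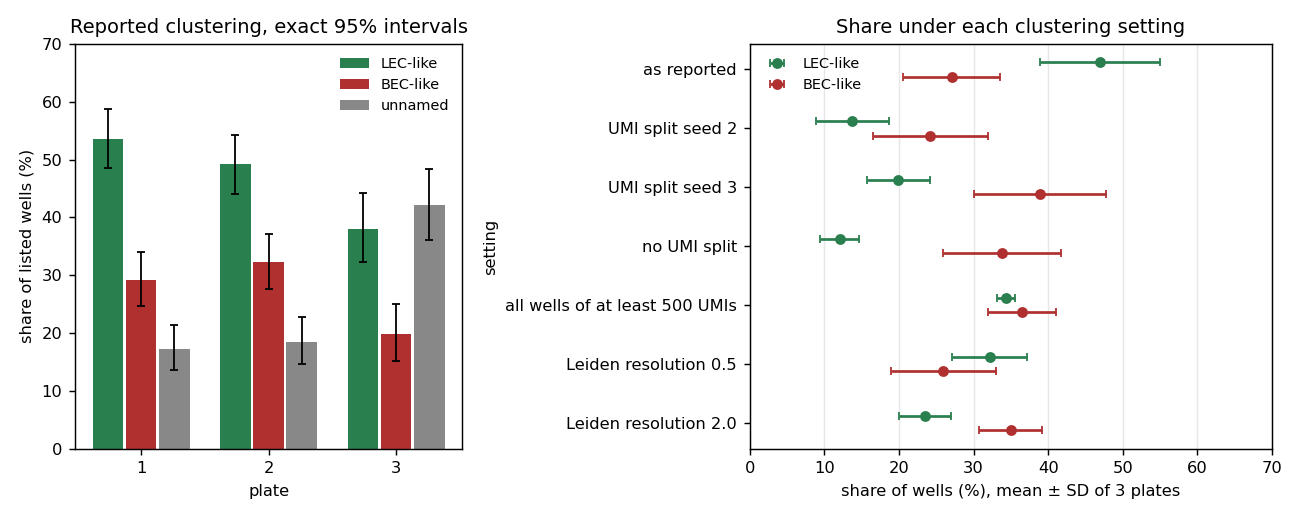
Shares of wells per class: left, the share of listed wells in each plate with exact 95% intervals, LEC-like 38.1% to 53.6% and BEC-like 19.8% to 32.3%. Right, mean ± SD of 3 plates for each clustering setting, with the LEC-like share between 12.09% and 47.0%.

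The LEC-like share depended on how the wells were clustered and on how the clusters were named. It was 13.8% and 19.9% with other random splits of the UMIs, 12.09% without a split, 34.4% in wells of at least 500 UMIs, and 32.2% and 23.5% at resolutions 0.5 and 2.0. Under each of these settings, some clusters met the LEC-like marker levels and stayed unnamed through markers of other cell types among their leading genes. They held 176 and 153 wells with seed 2, 116, 105 and 88 with seed 3, and 198 without a split. At resolution 0.5 such a cluster held 347 wells. Shares that include these clusters were not computed. At the reported settings, the largest LEC-like cluster, of 265 wells, passed the naming rule narrowly. It had 7 lymphatic and 7 blood markers raised and no lymphatic marker among its leading genes (erfl3, lgi2a, PRDM16). The other, of 232 wells, owed its name to a low mean log2 level of blood markers (-1.36). In wells of at least 500 UMIs, 154 of the 245 LEC-like wells formed a cluster that owed its name to low blood markers too (-1.30). Its lymphatic markers were also lower than in the wells outside it, at a mean log2 level of -0.39. Among the reported clusters, the larger BEC-like one, of 191 wells, was led by the globin genes hbae1, hbbe1.1, hbz and hbbe2 ahead of aqp8a.1. Over all listed wells, 3 wells held 75.5% of globin UMIs, and not all of them were BEC-like. Without them BEC-like wells of plate 2 went from 124 to 123. LEC-like wells went from 206 to 205 in plate 1 and from 189 to 188 in plate 2. No sample or condition is compared through these shares.

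LEC-like and BEC-like wells were compared first, since a passage from lymphatic to blood vessel identity would run between them. LEC-like sums had more cxcl12a, which encodes a chemokine that binds Cxcr4, at 718 ± 208 against 98.0 ± 95.6 CPM (SD, n = 3), a 5.94-fold difference by edgeR. They also had more wnt16, a Wnt ligand gene (3.18-fold), hapln3, which links hyaluronan to proteoglycans (5.22-fold), and the lysosomal protease genes lgmn (2.84-fold) and ctsla (1.98-fold). BEC-like sums had more rbp7b, a retinol-binding protein gene (11.5-fold, from 33 against 5 UMIs), epas1b, a hypoxia-inducible factor gene (3.18-fold), lpl, which encodes lipoprotein lipase (2.86-fold), and fabp11a, a fatty acid-binding protein gene (1.89-fold). The adhesion genes cdh5, for VE-cadherin, and pecam1 were higher in BEC-like sums as well, cdh5 in 2 of 3 plates and pecam1 in all 3. In plates 1, 2 and 3, cdh5 stood at 175, 287 and 719 CPM in LEC-like and at 917, 1002 and 683 in BEC-like sums. The SE and p given below for cdh5 do not measure that spread.

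Of 1093 genes other than naming markers, 56 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 31 higher in LEC-like and 25 higher in BEC-like sums. For cxcl12a the log2 fold change was 2.57 (SE 0.29, adjusted p = 5.9e-16), for wnt16 1.67 (SE 0.29, adjusted p = 9.6e-07), for fabp11a -0.91 (SE 0.09, adjusted p = 1.1e-22) and for cdh5 -1.69 (SE 0.23, adjusted p = 1.4e-11). Others of the named genes that were higher in LEC-like sums were chaf1a, a chromatin assembly factor gene of DNA replication, myhz1.3, a fast muscle myosin gene, cst14a.2, a cystatin gene, the actin regulator gene cotl1, vim (vimentin), txn (thioredoxin), marcksl1b and tnfaip2b, with log2 changes of 1.15 to 1.87. Others higher in BEC-like sums were aoc2, rbpms2b, CD93, serpinh1a, ppap2b, hopx, rgcc and gpm6aa, with log2 changes of -1.59 to -0.77. Muscle markers reached 274 ± 222 CPM in LEC-like and 73.2 ± 16.6 in BEC-like sums, beside which the 3.09-fold difference of myhz1.3 stands. In plates 1, 2 and 3 the markers stood at 512, 237 and 71.9 CPM in LEC-like and 91.7, 59.7 and 68.3 in BEC-like sums. The gene myhz1.3 stood at 548, 682 and 575 against 183, 203 and 205 CPM, and was not tested apart from stray muscle RNA. Fibroblast markers stood at 357 ± 335 and 119 ± 135.

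**Figure D2:**
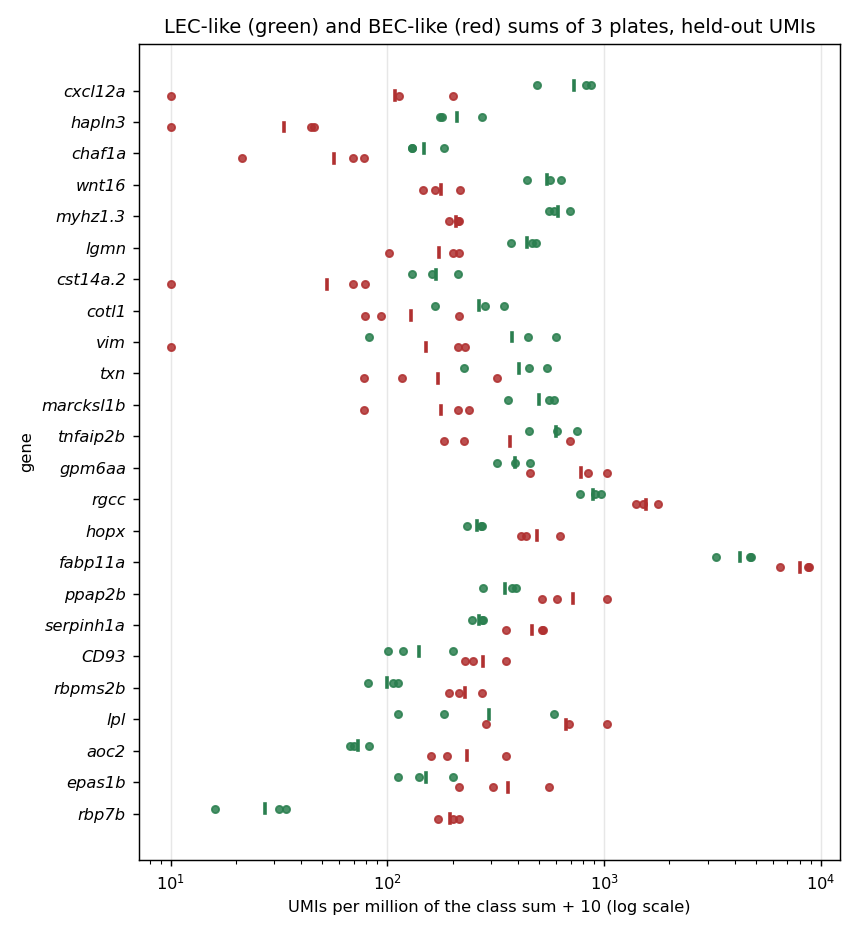
Genes with the largest differences between LEC-like (green) and BEC-like (red) sums, where each point is a plate (CPM plus 10, log axis) and each bar the mean of 3 plates; cxcl12a lies at 479 to 862 in LEC-like and 0 to 191 in BEC-like sums, before 10 is added.

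The genes cxcl12a, ctsla, fabp11a and cdh5 were called in the same direction under all 7 other ways of defining the classes, and wnt16 and myhz1.3 under the 6 that tested them. The direction of vim was opposite in 3 of 6, and those of col4a1 and ppap2b in 1 of 7 (seed 2). Calls of other named genes were less stable. No other definition called chaf1a, cst14a.2 or vim, which 1, 2 and 6 tested. The call was kept in 1 of 3 for aoc2, 1 of 4 for cotl1, 1 of 6 for serpinh1a and 1 of 7 for cebpb. It was kept in 2 of 6 for txn and 2 of 7 for ppap2b. Only 2 definitions tested rbp7b, and both called it. Without the plate block 29 genes were called, DESeq2 called 8 of the 56 and no others, and leaving out plate 1, 2 or 3 left 0 (52 at an unadjusted p under 0.05), 3 or 19. Over the other class definitions the count ranged from 14 at resolution 2.0 to 291 in wells of at least 500 UMIs. Most LEC-like wells of that last setting were in a cluster named through low blood markers. The count was 25 without an expression filter and 15 within the malat1-rich clusters alone.

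Of 10 gene lists tested between the classes 2 were called, for transport and for endocytosis, and both only at the preset correlation. In the transport and barrier list, 3 of 5 measured members fell in LEC-like relative to BEC-like sums and 2 did not pass (4 when adjusted over the list alone). The 3 were fabp11a, lpl and cav1, the last a caveolar coat gene. Camera gave an adjusted p of 1.8e-07, against an adjusted p = 0.565 with an estimated correlation and 0.155 by fry. In the scavenging and endocytosis list, 2 of 10 members rose, ctsla and lgmn, and 8 did not pass (2 when adjusted over the list alone). Its camera adjusted p was 0.0259, against an adjusted p = 0.584 with an estimated correlation, 0.243 by fry and 0.227 by camera without plate 2. Macrophage markers were higher in LEC-like sums too, at 36.2, 115 and 575 CPM in plates 1, 2 and 3 against 11.5, 11.9 and 68.3, and the protease genes were not tested apart from them.

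None of the other 8 lists was called by camera. In the junction list 2 of 9 members fell, cdh5 and pecam1 (3 when adjusted over the list alone), at a camera adjusted p of 0.0675. In the actin list 1 of 20 rose, vim (2 when adjusted over the list alone), at 0.0663. In the basement membrane list 1 of 6 fell, col4a1, a type IV collagen gene (2 when adjusted over the list alone), at 0.524. In the dissociation stress list 1 of 22 rose, cebpb (0 when adjusted over the list alone), at a camera adjusted p of 0.818 and a fry adjusted p of 0.0032, with a median log2 change of 0.004. No member passed among 6 Notch, 7 SoxF and ETS, 5 glycolysis and 16 oxidative phosphorylation genes (0 in each when adjusted over the list alone), at camera adjusted p-values of 0.818, 0.210, 0.524 and 0.246. The glycolysis list had a fry adjusted p of 0.0054, with lower levels in LEC-like sums.

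Regulators of vessel identity were close to the detection limit. The lymphatic master regulator gene prox1a had 23 UMIs in LEC-like and 4 in BEC-like sums, too few for the test, as were nr2f2 (26 and 11), sox17 (9 and 3), sox18 (4 and 5) and the proliferation marker gene mki67 (34 and 10). Of the SoxF gene sox7, sums held 341 ± 35.2 CPM in LEC-like and 605 ± 186 in BEC-like wells (adjusted p = 0.141, edgeR). For pcna, a replication clamp gene, they held 401 ± 15.2 and 218 ± 122 (adjusted p = 0.120, edgeR). Neither difference passed the threshold, and in no other contrast did sox7 or pcna have an adjusted p under 0.299. Under other class definitions sox7 kept its direction in 7 of 7 and pcna in 6 of 6, and each was called in 1.

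Each class split into a cluster rich and a cluster poor in malat1, a nuclear long noncoding RNA; the clusters are called so from levels seen in the data. Among LEC-like wells malat1 stood at 13307 ± 1731 CPM in the rich and 2402 ± 763 in the poor cluster (SD, n = 3; log2 2.69, SE 0.11, adjusted p = 1.0e-08, edgeR). The rich cluster also had more of the Notch ligand genes dll4, a naming marker (536 against 143 CPM), and jag2b (log2 1.75), the junction genes cdh5 (log2 1.81) and esama (2.73-fold), col4a2 (8.98-fold), the transcription factor genes mef2aa (6.07-fold) and ebf1a (5.37-fold) and the AP-1 gene fosb (6.66-fold). The poor cluster had more chaf1a, the cytochrome oxidase subunit gene cox7c, the translation initiation gene eif3ba and the histone variant gene h2afvb, with 4.43-, 2.78-, 2.16- and 2.14-fold differences. Of 795 genes 102 were called, 72 higher in the rich and 30 higher in the poor cluster, of which 13 encode ribosomal proteins; the 102 include the naming markers dll4, kdrl and stab1. The gene jag2b, outside the rule for named genes, was chosen after its values were seen.

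The other named genes of this contrast were NAV1, prkd3, pcdh19, rapgef2, tmem108, ZNF423 and dedd1, higher in the rich cluster (log2 2.16 to 3.96), and cotl1, txn, ppiab, tubb4b, hmgn2, cirbpa, s100a10b and ybx1, higher in the poor cluster (log2 -1.35 to -0.56). In the junction list 2 of 8 members rose in the rich cluster (4 when adjusted over the list alone), at a camera adjusted p of 0.0332 and an adjusted p = 0.480 with an estimated correlation. In the dissociation stress list 2 of 21 rose, fosb and fosab (2 when adjusted over the list alone), and camera did not call the list. Ribosomal protein mRNA made up 14.3% ± 0.110 of UMIs in the rich and 19.2% ± 1.80 in the poor cluster, and median depth per well averaged 883 ± 253 and 1134.5 ± 450 UMIs over the plates. DESeq2 called 9 of the 102 genes, 22 were called without an expression filter, and leaving out plate 1 or 2 left 1. With other random splits a pair of LEC-like clusters that matched the reported pair came only from seed 3, with 19 genes called, 9 of them shared, and s100a10b turned in direction.

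The BEC-like clusters, compared after the data were seen, differed in part through the same genes. In the malat1-rich cluster spns2, a sphingosine-1-phosphate transporter gene, was 4.63-fold higher, cdh5 3.20-fold, the plectin gene plecb 3.25-fold, lpl 2.60-fold and id1, a BMP-responsive gene, 2.23-fold, and so were the naming markers dll4 (3.40-fold) and plvapa (3.60-fold). Higher there too were isl1l, rapgef2, macf1a, klf6a, ppap2b and fgd5a (log2 1.22 to 2.03). The poor cluster had more gnb2l1, icn and actb1, by 1.54-, 1.49- and 1.44-fold. Of 259 genes 25 were called, 21 higher in the rich and 4 in the poor cluster, with the naming markers aqp8a.1, plvapa, dll4, aqp1a.1 and kdrl among the 21. Of 256 genes tested in both classes, 54 and 22 were called and 13 in both, against 4.64 for independent lists, and the 13 moved the same way. They were malat1, cdh5, col4a1, fgd5a, id1, igfbp1a, plecb, rapgef2, rgcc, spns2 and zgc:154040, with the naming markers dll4 and kdrl. Ribosomal protein mRNA made up 13.7% ± 0.685 and 17.5% ± 0.567 of UMIs. Arterial markers, dll4 among them, were higher in the rich cluster in every plate of both classes, at 2017 ± 554 against 628 ± 301 CPM in LEC-like and 2640.3 ± 569 against 1178 ± 326 in BEC-like wells. Most pan-endothelial markers, pooled over plates, were higher there too, so the shift was not confined to arterial genes. Without an expression filter 35 genes were called, 2 higher in the rich and 33 in the poor cluster, and 5 of the 25 kept their call. DESeq2 called 6 genes, 147 were called without the split, 2 at resolution 2.0, and 2 and 54 without plates 2 and 3.

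**Figure D3:**
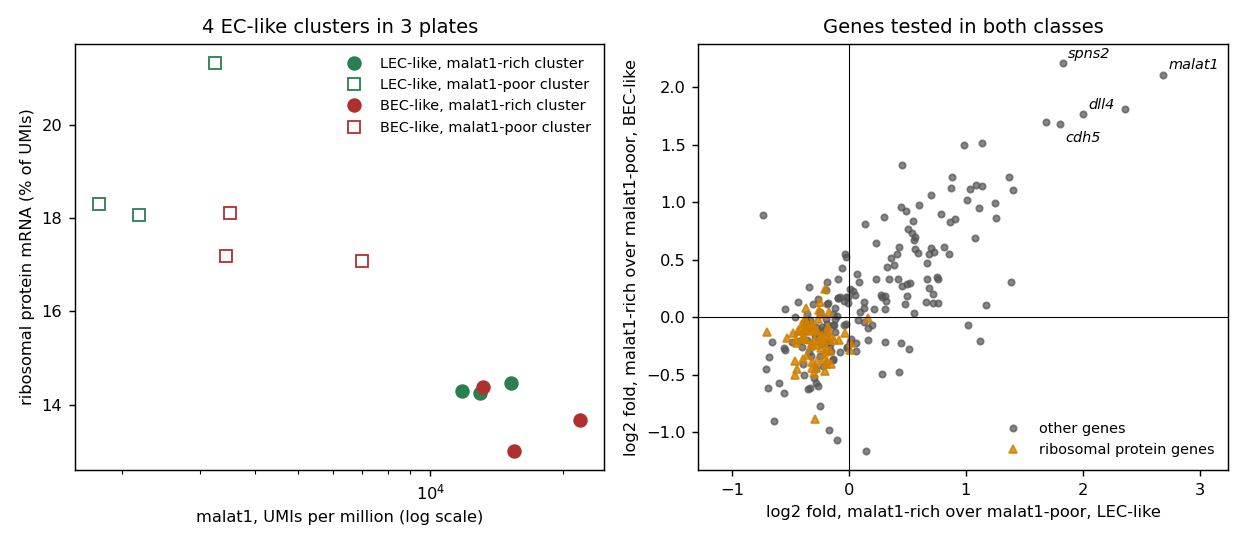
Clusters rich and poor in malat1: left, malat1 (CPM, log axis) against the ribosomal protein share of UMIs for 4 clusters in 3 plates, with filled symbols for malat1-rich clusters at 13.0% to 14.5% and open symbols for malat1-poor clusters at 17.1% to 21.3%. Right, log2 fold changes between rich and poor cluster of genes tested in both classes, with Spearman's rho of 0.664 over 255 genes without malat1.

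Few genes were called between the unnamed clusters and the endothelial classes. The sums of these clusters held only 1978 to 10169 UMIs per plate, so few calls do not show likeness. Clusters 5 and 6 met the LEC-like marker levels, and markers of other cell types among their top 10 genes kept them unnamed. Cluster 3, of 145 wells with a median of 109 UMIs, had less malat1, at 3749 ± 1791 against 8070 ± 3395 CPM (adjusted p = 0.00033, edgeR), and more of the keratin gene krt15, at 917 ± 380 against 246 ± 49.7 (adjusted p = 0.0028). Cluster 5, of 57 wells, had more MEPCE and the actin genes actb2 and actb1, by 3.78-, 2.45- and 2.00-fold. In plate 2 these levels were close, at 871 against 852, 8272 against 7224 and 3918 against 3793 CPM. Neutrophil markers of this cluster stood at 0 CPM in the same plate. Cluster 6, of 47 wells, had less malat1 (1.90-fold) and less si:dkey-238c7.12 (log2 0.87 higher in endothelial sums), a gene outside the naming rule and chosen after its values were seen. The naming marker aqp8a.1 was lower in clusters 3 and 6, by 2.54- and 2.93-fold. These 2, 3 and 2 genes were the whole of the calls among 396, 391 and 399 genes. DESeq2 called 0 (15 at an unadjusted p under 0.05), 2 and 1, the last being neither of the genes reported for cluster 6 and higher in that cluster. Leaving out plates gave 0 to 4, 0 to 15 and 0 to 2 (23 to 66 at an unadjusted p under 0.05 where 0 were called). No block gave 1, 3 and 0 (27 at an unadjusted p under 0.05), and no expression filter gave 129, 8 and 110, which kept 1, 0 and 2 of the reported calls. Without that filter the log2 changes of the shared genes moved by a median of 1.21, 1.41 and 1.11, a shift of the scaling that these counts include.

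In cluster 5, 2 of 12 members of the actin list were higher than in endothelial sums (4 when adjusted over the list alone), at a camera adjusted p of 0.00084 and an adjusted p = 0.630 with an estimated correlation. These differences were not tested apart from the neutrophil-rich wells. Neutrophil markers reached 10141 ± 9906 CPM in cluster 5 (19794, 0 and 10629 in plates 1, 2 and 3), against 210 ± 156 in LEC-like and 156 ± 125 in BEC-like sums, and 22.8% of its wells had a neutrophil UMI. Its leading genes were lyz, mmp9 and mmp13a, for lysozyme and matrix metalloproteinases, and plate 1 gave 148 of the lyz UMIs in listed wells, against 11 and 1 in plates 2 and 3. Markers shared by all endothelium stood at 5557 ± 798 in cluster 5, 7579 ± 1942 in cluster 3 and 9883 ± 240 in cluster 6, against 8137 ± 620 and 10906 ± 1307 in LEC-like and BEC-like sums.

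The keratinocyte list stood at 4400.3 ± 1284 in LEC-like, 4112 ± 416 in BEC-like and 2674 to 4616 CPM in the unnamed clusters, nearly all of it from icn (2095 to 4642 CPM by cluster) and krt4 (349 to 980). Its other members, among them krt5, cdh1, epcam and tp63, had at most 54.5 CPM in any cluster, so the sum does not show keratinocyte RNA. Arterial markers stood at 1306 ± 305 and 1587 ± 345 in LEC-like and BEC-like sums, venous markers at 1656 ± 269 and 1305 ± 303, and mural markers at 613 ± 59.1 and 777 ± 333, mostly from rgs5b, with acta2, cspg4 and cald1b at 0. Macrophage markers were at 242 ± 291 and 30.6 ± 32.7, thrombocyte markers at 164 ± 152 and 221 ± 342, and erythroid markers at 51.1 ± 68.8 and 82.3 ± 78.7. The erythroid list lacks hbae1, hbz, hbbe1.1 and hbbe2 and so understates red cell RNA; all globin genes together had 784 UMIs in the listed wells, 592 of them in 3 wells. Osteoblast, lymphocyte, pigment and glial or neuronal markers had at most 10 UMIs in any class. None of these marker levels was tested between classes.

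UMIs of markers planned as lymphatic-only (prox1a, lyve1b, stab1, mrc1a, flt4) and of 9 planned as blood-only were often found in the same well, as cells passing between both identities would show and as doublets or free RNA would also give. In 597 endothelial wells thinned to 500 UMIs, 25.6% ± 0.936 had both kinds (SD, n = 3), against 26.6% ± 1.56 expected if both were detected independently. The ratio was 0.961 ± 0.0275 and below 1 in all 3 plates, and 189 shallower wells were left out. The share was 10.8% at 250 UMIs, 48.2% at 1000 UMIs and 14.3% without kdrl and flt4. Of these flt4 was not called between the classes, at 614 ± 58.2 CPM in LEC-like and 493 ± 170 in BEC-like sums (adjusted p = 0.371, edgeR). Its level was higher in LEC-like sums under all 6 other class definitions that tested it, and 3 of them called it. Without thinning 40.6% ± 8.07 of 786 wells had both kinds, with a ratio of 1.07 ± 0.0727, above 1 in all 3 plates. Without plvapb, a blood marker gene detected in both classes, the share was 13.2% ± 3.81 and the ratio 0.759 ± 0.0464. In 6 wells rich in neutrophil markers, at a median of 1369 UMIs against 1007 in endothelial wells, 2 had a blood-only and 0 a lymphatic-only UMI. The exact 95% interval for 0 of 6 wells with both kinds reaches 45.9%.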

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

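Of the tests in this part, the count of neutrophil and globin UMIs at matching coordinates was chosen after the result was seen. The values for wells off the authors' list involve no test.

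The wells of plate 3 that the authors left off their list held signal although the reported contrasts do not use them. Only the alternative with all wells of at least 500 UMIs includes those of that depth. These 116 wells had 595 UMIs of pan-endothelial markers, 600 UMIs of aqp8a.1, a water channel gene of the BEC-like class, and 229 UMIs of neutrophil markers. What drew attention is signal in wells outside the main measurement, above the limit that a count of 0 allows. In the 45 of them with at least 500 UMIs, pan-endothelial markers stood at 7822 CPM, blood markers at 14979 CPM and neutrophil markers at 3494 CPM. The 112 listed wells of that depth in plate 3 had 9309, 10996 and 2386 CPM. Of the 229 neutrophil UMIs, 188 came from 3 wells. The rule by which wells were left off the list is not given in the sources used here, and these differences were not tested.

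Transcripts of a few wells reappeared at the same coordinate of other plates. For 12 wells rich in neutrophil or globin mRNA, 3 of them off the authors' list, the matching wells of the other plates held 40 UMIs of those markers, against a mean of 3.69 at random coordinates (permutation p = 6.0e-05, 100000 permutations). Of these UMIs 13, 12 and 11 belonged to 3 of the wells, and the other 9 wells gave 0 to 3 each. Over 1454 genes, wells sharing a coordinate had a mean correlation of 0.0453, against 0.00045 (SD 0.00178) for shuffled wells (p = 0.001, the smallest that 1000 shuffles allow), and all 384 coordinates carry the same barcode on every plate. Shared depth as the whole cause was argued against, since wells thinned to 300 UMIs still had a correlation of 0.0159 against -2.9e-05 (SD 0.0019) when shuffled (p = 0.001). Reads carried between plates under a shared barcode could give these values, an effect of well position stays open, and no biological explanation was tested. Carried reads would also leave the plates less independent than the tests between classes take them to be, by an amount that was not measured.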

How the results depend on the processing

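Alternatives chosen after seeing the data were the BEC-like cluster contrast, the contrasts within malat1-rich or malat1-poor clusters, leaving out globin-rich wells, and co-detection without plvapb or within 1 class. Without the plate block 29 genes were called between LEC-like and BEC-like sums in place of 56, and 1 and 0 for unnamed clusters 3 and 6 in place of 2 each. Unnamed cluster 5 kept 3, and 95 and 27 were called between the LEC-like and BEC-like clusters. The cause of the changes listed here was not tested unless one is given.

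The count between LEC-like and BEC-like sums was 8 by DESeq2, 25 without an expression filter, 30 with seed 2, 291 in wells of at least 500 UMIs, 17 and 14 at resolutions 0.5 and 2.0, 102 with classes by marker sums and 15 within the malat1-rich clusters. It was 0 to 19 with a plate left out, where fewer samples leave less power. It stayed within 1.5 times 56 with DESeq2 size factors (40), seed 3 (71), no split (58), no globin-rich wells (52) and only malat1-poor clusters (51). Those 291 calls shared 51 with the 56, and among the 56 genes that could be tested under other class definitions, 27 of 30 (seed 2) up to all kept their sign.

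For unnamed cluster 3 the count was 0 by DESeq2, 129 without a filter and 0 to 4 with a plate left out. For cluster 5 it was 8 without a filter and 0 to 15 with a plate left out. For cluster 6 it was 1 by DESeq2, 1 with its size factors, 110 without a filter and 0 to 2 with a plate left out. For the LEC-like clusters it was 9 by DESeq2, 22 without a filter, 19 with seed 3 and 1 to 148 with a plate left out. For the BEC-like clusters it was 6 by DESeq2, 35 without a filter (2 higher in the rich cluster), 147 without a split, 2 at resolution 2.0 and 2 to 54 with a plate left out. Without a filter the median log2 change of the shared genes moved by 1.21, 1.41 and 1.11 for unnamed clusters 3, 5 and 6, by -0.18 and -0.75 between the LEC-like and BEC-like clusters and by 0.16 between the classes. Clusters of other settings were matched to the reported ones by the majority of shared wells. In the settings not named here, all clusters of a class matched the same reported cluster, or a matched group had only 7 wells in a plate (LEC-like, resolution 2.0). Unnamed clusters were not matched across clusterings, so the alternatives planned for them there were not run.

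Of 2 gene lists called, 1 to 2 stayed with a plate left out, 1 within the malat1-rich clusters and 0 with an estimated correlation.

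The LEC-like share of 47.0% was 13.8% and 19.9% with seeds 2 and 3, 12.09% without a split, 34.4% in wells of at least 500 UMIs, and 32.2% and 23.5% at resolutions 0.5 and 2.0. The BEC-like share of 27.1% was 38.9% with seed 3, 33.8% without a split, 36.5% in wells of at least 500 UMIs and 35.0% at resolution 2.0, and 24.2% and 25.9% with seed 2 and resolution 0.5. The unnamed share of 25.9% was 62.0% and 41.1% with seeds 2 and 3, 54.1% without a split, and 41.9% and 40.0% at resolutions 0.5 and 2.0. In each of these other clusterings, some clusters with LEC-like marker levels stayed unnamed through markers of other cell types, so naming entered these shares too. With a plate left out the LEC-like, BEC-like and unnamed shares were 43.6% to 51.4%, 24.5% to 30.7% and 17.8% to 30.3%.

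The share of wells with both lymphatic-only and blood-only UMIs, 25.6% at 500 UMIs, followed depth: 10.8% at 250 UMIs, 48.2% at 1000 UMIs and 40.6% unthinned, with ratios to independent detection of 0.877, 1.00 and 1.07 in place of 0.961. It was 14.3% without kdrl and flt4, 22.4% in wells of at least 500 UMIs, 13.2% without plvapb (ratio 0.759), and 28.1% and 21.5% in LEC-like and BEC-like wells alone. With a plate left out the share and the ratio moved by less than 1 SD.

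Some genes changed sign between LEC-like and BEC-like sums. The log2 change of col4a1 was 0.27 and of ppap2b 0.15 with seed 2. For vim it was -0.64 with seed 3, -1.32 in wells of at least 500 UMIs and -0.82 with classes by marker sums. For the naming markers cxcr4a and plvapb it was -1.96 and 0.39 with seed 3, and -1.99 and 0.014 in wells of at least 500 UMIs. Without a filter actb1 and actb2 changed to 0.55 and 0.28 for unnamed cluster 5, where the shared genes moved by a median of 1.41, so that these changes of sign are not specific to actin genes. Between the LEC-like clusters s100a10b changed to 0.062 with seed 3. Of 723 values of named genes between LEC-like and BEC-like sums under an alternative, 471 kept direction and side of the threshold, 236 lost the call in the same direction and 7 gained one. Between the LEC-like clusters 194 of 297 were kept and 100 lost, and between the BEC-like clusters 119 of 186 and 67.

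Depth set the limits of detection. Plate 3 gave 41743 held-out UMIs of LEC-like and 14637 of BEC-like wells, against 165934 and 87243 in plate 1, and its cluster 6 sum held 1978.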

Other observations

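Of the tests in this part, the correlation between the malat1 contrasts, the comparison with free RNA and the counts over regrouped sums were chosen after the results were seen, as was the contrast of the BEC-like clusters itself.

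The clusters rich in malat1 shared a profile across both endothelial classes: over genes tested in both, log2 changes correlated at Spearman's rho = 0.664 (255 genes, 79.2% with the same sign), with cdh5, spns2, dll4 and id1 higher and ribosomal protein mRNA lower in both rich clusters. Depth as the whole cause was argued against: in wells matched on depth, malat1 was still 2.56-fold higher or more in every plate and class (highest 7.71-fold). A loss of cytoplasmic RNA from damaged cells, which would leave nuclear RNA such as malat1 enriched, may give the same shared profile and cannot be told apart from a cell state, because both predict a correlation like the 0.664 seen. Mitochondrial mRNA, often a raised share in damaged cells, was lower in the rich clusters, at 4.35% ± 0.0227 against 5.15% ± 0.433 of UMIs in LEC-like and 4.35% ± 0.387 against 4.86% ± 0.520 in BEC-like wells, which does not exclude damage that also loses mitochondria. A cell state stays open as well, untested, with arterial markers higher in the rich cluster in every plate of both classes. Pooled over plates, most pan-endothelial markers were higher there too, with egfl7 at 529 against 271 CPM in LEC-like and 559 against 280 in BEC-like wells. Those lower were fli1b, tek, rasip1 and plvapb in LEC-like and erg, sox18 and she in BEC-like wells. In LEC-like wells the venous markers sele and vwf were higher as well. The shift was therefore not confined to arterial genes.

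Wells with both lymphatic-only and blood-only UMIs were no more frequent than independent detection gives, at a ratio of 0.961 over the plates in wells of equal depth. Wells holding 2 cells may add to them, since wells with both kinds had up to 1.23 times the depth of wells with 1 kind (1.19, 1.01 and 1.23 in plates 1, 2 and 3), yet the same depth difference would follow from large cells. Free RNA or carried reads, which would also be detected independently of a cell's identity, cannot be told apart from low expression in the cells by a ratio that was 0.961 at equal depth, 0.759 without plvapb and 1.07 unthinned. The wells rich in neutrophil mRNA that could set that background numbered 6, too few to decide. Cells passing from lymphatic to blood identity stay open and were not excluded or singled out by these values.

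Each contrast was repeated over the 10 ways of dividing its 6 sums into groups of 3, so that the share of splits with as many genes called could not fall under 0.1. Most of these splits put both sums of some plate in the same group and so break the pairing by plate. Among those that keep the pairing, that share has a higher floor still. Only 1 split, the real one, reached the count in each contrast. Every other split mixes the classes within its groups, so a class difference widens the spread within groups and low counts follow. Since finished sums and not wells were regrouped, these counts cannot show whether the clustering grouped wells by chance. The real and the highest other counts were 56 and 0 for LEC-like against BEC-like, 102 and 0 for the LEC-like clusters, and 25 and 0 for the BEC-like clusters. They were 2 and 1, 3 and 2, and 2 and 0 for unnamed clusters 3, 5 and 6. Among splits that kept the pairing, the highest other counts were 0 and 1 for clusters 3 and 5.

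Neutrophil mRNA was concentrated in few wells. On the authors' list 6 wells with more than 20 neutrophil marker UMIs (1, 0 and 5 in plates 1, 2 and 3) held 71.5% of the 713 such UMIs. Of the 510 UMIs in these 6 wells, 1 well of plate 1 alone held 309. Pooled over the 6 wells, and so weighted by that 1 well, neutrophil markers reached 51750 CPM and pan-endothelial markers 1116 CPM. Endothelial wells had 143 and 8700 CPM. A neutrophil-like class appeared only in wells of at least 500 UMIs (11 wells) and at resolution 2.0 (13 wells), too unevenly spread over plates for a test. Globin mRNA was concentrated as well, with 75.5% of 784 UMIs in 3 wells.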
